A study of Mus musculus with 8 samples.

How the data were processed

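Total RNA was taken from the livers of 8 female mice, 4 WT and 4 F2_outcross, with a kit for lipid-rich tissue, and sequenced after a strand-specific library preparation, per the labels' protocols. The submitters' processing notes name cutadapt, HISAT2 and DESeq2 and the mouse genome build GRCm38, with no versions and no roles. The read counter, its strand setting and the gene annotation are not given in the sources used here, so reads shared by near-identical or overlapping genes may have been assigned in ways that cannot be traced. The deposited table, per the file headers a table of gene symbols and 8 libraries, holds values that the authors placed on a log2 scale. Its lowest value, -3.32, is log2 of 0.1, and on subtracting 0.1 from 2 raised to each value, 100% of values lay within 0.001 reads of a whole multiple of one step per library. Each value was therefore read as log2 of a size-factor-normalized count plus 0.1, and the steps gave the whole reads of each library. Build GRCm38 coordinates, exonic lengths and GC content came from GENCODE M21 and from RefSeq where a symbol was missing there. Positions were found for 14301 of 14390 tested symbols.

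The table held 25069 lines, of which 395 had no symbol. Those lines took 0.611% to 1.22% of a library's reads and were left out of tests. In 8 cases a symbol stood on more than 1 line, and 916 lines were at the floor in every library. No 2 libraries were copies of each other, since the chi-square per degree of freedom between any 2 was 39.6 or more, so each library was counted as 1 replicate. One read was worth 0.779 to 1.04 normalized reads, so the depth allows a gene with 10 normalized reads to rest on about that many reads. Read floors and counts cover counting error only.

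The main comparison was fixed before the data were examined. Deposited values were returned to the normalized scale and analysed as log2(value + 1), so fold changes of low genes are understated. Genes with at least 10 normalized reads in at least 4 of the 8 libraries were kept (14390 genes). limma 3.58.1 in R 4.3.3 was used (lmFit, eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) with group as the only term, since the labels give no batch. Every adjusted p of a single gene is from this limma fit unless another setting is named. Errors given with log2 fold changes are moderated standard errors, with n = 4 per group, and errors given with normalized reads are SDs. The plan had assumed a table of linear normalized values, and the log2 values were converted to that scale first. On simulated data with the real means, limma recovered 37.3%, 72.7% and 87.9% of genes changed 1.5-, 2- and 4-fold among 14438 genes, with 5.07% false calls among 138, and called 0 of 14416 genes where none had been changed. Each gene was drawn independently, with no correlation between genes and no factor shared within a library. These rates therefore need not hold for the real data.

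Gene lists, 40 in all, were written before the data were examined. The 36 with at least 5 tested members were compared with camera (preset correlation 0.01, two-sided, adjusted over the lists), and again with an estimated correlation and with fry. For each list the number of members past the threshold is given over all genes tested and adjusted over the list alone. Adipocyte markers (0 of 5 passed the filter) and the sex check list (1 tested, Xist) had too few members for a set test. Shares of cell types were not estimated beyond the marker lists. The spread between animals was compared as the median log2 ratio of SDs, with an exact permutation of residuals over all 70 assignments. Genes named in the text follow a rule written before the data were examined: the 12 largest changes in each direction among genes past the threshold whose groups did not overlap, leaving out genes whose names mark predicted models or pseudogenes (37 changed genes, only counted), up to 4 members of each list with the smallest p, and Khdc3 with the sex check genes. Single-gene results of 2 genes that the rule selects are not reported here. The chromosome 17 genes and pseudogenes outside that rule were named after their values were seen.

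Alternatives fixed in advance were pseudocounts of 0.5 and 5, no filter on low values, a mean of at least 50, TMM, quantile and upper quartile scaling, robust moderation, library weights, a threshold of 0.10 and leaving out each library in turn. Added after the data were seen were the log2 values as deposited, limma voom on the recovered reads, removal of length and GC trends with loess curves per library, and removal of the chromosome 17 window. Planned tests with edgeR and DESeq2 on recovered reads were not run here, and limma voom on those reads was added instead. Pseudogenes with a GENCODE sequence were matched to parent genes with BLAST 2.17.0, so those found in RefSeq alone, Rps18-ps5 and Rps18-ps6 among them, were not matched. Windows of 3 Mb in steps of 0.5 Mb were compared with 10000 shuffles of the calls over the tested genes with a position. Annotation and figures used Python 3.11.15.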

Results

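Liver RNA was sequenced from 8 female mice, 4 in each of 2 groups. The WT animals had wild-type ancestors throughout. The F2_outcross animals were also wild type in genotype, but their mother's mother lacked Khdc3, a gene of the oocyte and early embryo. The comparison asks whether the liver transcriptome of a wild-type female differs when a maternal grandmother lacked that gene. Each library held between 28028650 (WT replicate 3) and 35843972 reads (WT replicate 1) assigned to genes of the deposited table. The totals were 32361600 ± 4036730 reads in WT and 31721200 ± 1068130 in F2_outcross (mean ± SD, n = 4 per group; two-sided exact permutation p = 0.771, where the smallest possible p is 0.0286). The 10 genes with the most reads took 19.7 ± 1.61% of a library in WT and 18.8 ± 1.03% in F2_outcross (exact permutation p = 0.457). No litter, dam, collection hour, feeding state or sequencing batch is given in the sources used here, and the labels do not say how many litters the animals came from, so the p-values measure the spread between these samples.

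Khdc3 itself was at the floor of the measurement in both groups. WT replicate 1 had 1 read and the other 7 libraries had 0, against a floor of 3 reads per library, so no fold change is given. Among its partners in the subcortical maternal complex, a protein assembly of oocytes, Ooep had 0 reads in every library. Tle6 was at 40.3 ± 5.16 in WT and 31.9 ± 2.16 in F2_outcross normalized reads (mean ± SD, n = 4 per group) and Zbed3 at 104 ± 9.06 in WT and 122 ± 21.5 in F2_outcross, and neither passed the test (adjusted p = 0.400 and adjusted p = 0.461). Xist, the RNA that coats the inactive X chromosome, was at 20773 ± 3644 in WT and 22278 ± 6318 in F2_outcross normalized reads, and the lowest library, F2_outcross replicate 2, had 15608.

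**Figure D1:**
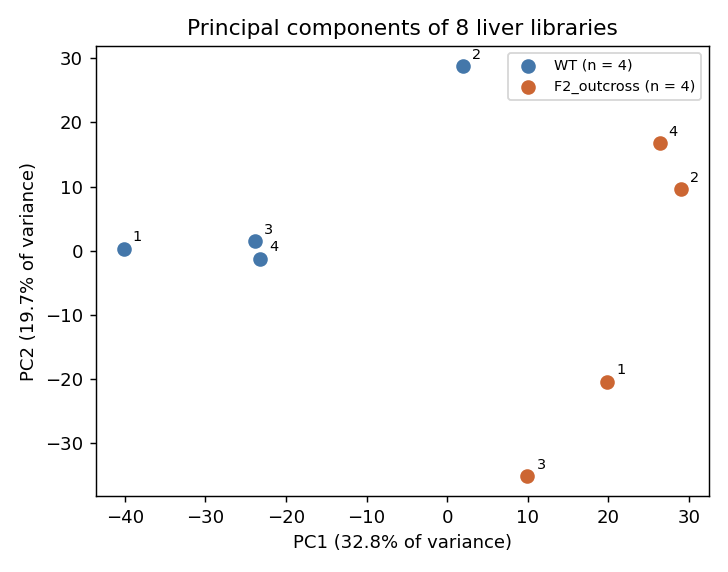
Principal components of log2 normalized reads over 14390 genes, with 1 point per library numbered by replicate and the axes giving component scores. F2_outcross libraries lay at 9.98 to 29.0 on the first component, 3 WT libraries at -40.1 to -23.2 and WT replicate 2 at 1.98.

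The first principal component, with 32.8% of the variance, placed all 4 F2_outcross libraries above every WT library, with WT replicate 2 closest to the F2_outcross libraries. Libraries of one group correlated with a median r of 0.984 across genes (12 pairs) and libraries of different groups with 0.978 (16 pairs). These are correlations across genes, which are not independent replicates. The spread between animals did not differ between the groups by the planned test. The median log2 ratio of the SD in F2_outcross to that in WT was -0.06, a ratio of 0.959 (two-sided exact permutation p = 0.971 over 70 assignments), and it was 0.41 without WT replicate 2 (exact p = 0.114) and 0.02 without WT replicate 1.

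Nnmt, which methylates nicotinamide with S-adenosylmethionine (chromosome 9, 48591877 to 48605153), rose 4.55-fold, from 1673 ± 381 to 7536 ± 1059 normalized reads (mean ± SD, n = 4 per group; log2 fold change 2.19 ± 0.15, adjusted p = 2.93e-05). Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6265612 to 6275633), rose 3.26-fold, from 3061 ± 1032 to 9911 ± 3454 normalized reads (log2 fold change 1.70 ± 0.26, adjusted p = 0.00733). Nrg4, a secreted ligand of the ErbB4 receptor (chromosome 9, 55220222 to 55326844), rose 3.55-fold (log2 fold change 1.83 ± 0.19, adjusted p = 0.000861), and Plin4, a coat protein of lipid droplets (chromosome 17, 56100591 to 56109803), rose 3.33-fold (log2 fold change 1.74 ± 0.23, adjusted p = 0.00286). In all, 383 of 14390 tested genes changed, 230 higher and 153 lower in F2_outcross (limma, Benjamini-Hochberg adjusted p under 0.05). With upper quartile scaling 198 were higher and 208 lower. Of the changed genes 125 changed at least 2-fold, 66 higher and 59 lower, and in 372 the 4 values of one group all lay above the 4 of the other. Of all tested genes 1720 had such groups, where chance gives 2.86%. The count rested on single libraries: it was 131 without WT replicate 1, 1077 without WT replicate 2, 120 without WT replicate 3, 132 without WT replicate 4, 140 without F2_outcross replicate 1 and 108 without F2_outcross replicate 2. 80 of the genes passed in each of the 8 fits that left a library out, 57 higher and 23 lower, among them Nnmt, Cyp7a1, Nrg4 and Plin4.

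**Figure D2:**
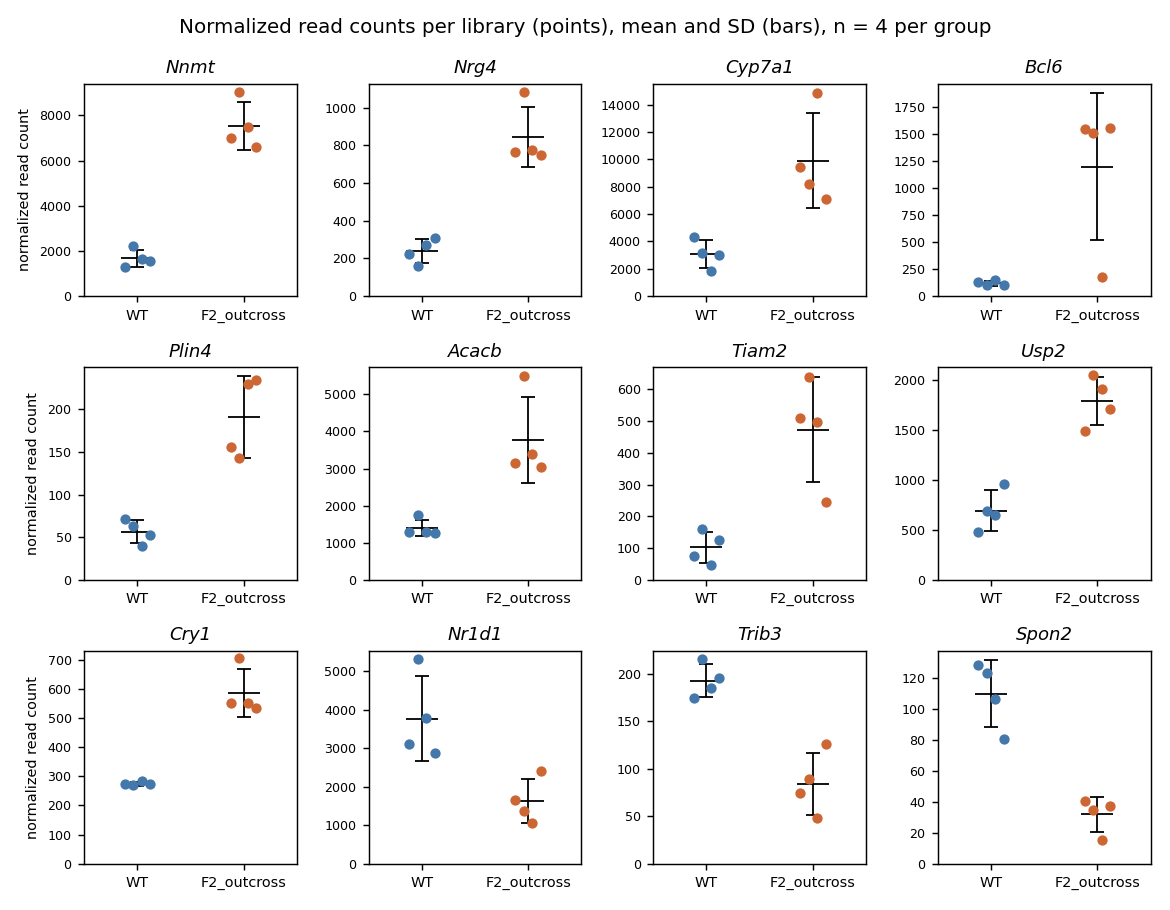
Normalized read counts of 12 changed genes in each library (points), with the mean and SD of each group (bars, n = 4). Nnmt lay at 6599 to 9025 in F2_outcross and at 1307 to 2207 in WT, and Bcl6 in F2_outcross replicate 3 lay at 174, near the WT values.

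The other genes among the 12 largest rises were of several kinds. Myom3, a protein of the muscle M-band, rose 8.09-fold to 55.5 ± 23.4 normalized reads (log2 fold change 3.02 ± 0.38, adjusted p = 0.00255). AI506816 rose 8.02-fold from 6.68 ± 4.05 (adjusted p = 0.0177), and Sftpa1, a surfactant protein, 3.24-fold from 8.17 ± 3.78 (adjusted p = 0.0399). Bcl6, a transcriptional repressor, was at 119.5 ± 23.2 in WT and 1196 ± 682 in F2_outcross (log2 fold change 2.91 ± 0.57, adjusted p = 0.0226). Its value was 174 in F2_outcross replicate 3 and between 1511 and 1553 in the other 3 F2_outcross libraries. Ren1, which encodes renin, rose 4.97-fold (log2 fold change 2.31 ± 0.54, adjusted p = 0.0422), and Tiam2, an activator of the small GTPase Rac, 4.80-fold (log2 fold change 2.26 ± 0.36, adjusted p = 0.00961). The remaining places went to H2-Eb1 and H2-T23 of the major histocompatibility complex, described with their neighbours on chromosome 17. Ren1 was at 946, 229, 953 and 161 in F2_outcross replicates 1 to 4 and at 50.6 to 129.5 in WT. AI506816 lost its call in 1 of the 8 fits that left a library out, Sftpa1 in 7, Bcl6 in 5 and Ren1 in 6, while Tiam2 passed in each such fit.

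The largest falls included several genes of immune cells. Ciita, the master activator of class II histocompatibility genes, was 3.89-fold lower (log2 fold change -1.96 ± 0.41, adjusted p = 0.0313), at 138 in F2_outcross replicate 3 and 27.8 to 36.0 in the other 3. Ighd, the heavy chain of immunoglobulin D, was 3.11-fold lower (log2 fold change -1.64 ± 0.37, adjusted p = 0.0377). S100a8, a calcium-binding protein of neutrophils, was 3.18-fold lower (log2 fold change -1.67 ± 0.35, adjusted p = 0.0313) and Ifi27l2a, an interferon-induced gene, 3.09-fold lower (log2 fold change -1.63 ± 0.38, adjusted p = 0.0434). Nox4, an NADPH oxidase, was 4.16-fold lower (log2 fold change -2.06 ± 0.37, adjusted p = 0.0180). Spon2, a secreted matrix protein, fell from 109.7 ± 21.7 to 31.9 ± 11.1 normalized reads (log2 fold change -1.81 ± 0.29, adjusted p = 0.00984). Nckap5 (-1.76 ± 0.39), Mal (-1.72 ± 0.40) and Septin3 (-1.67 ± 0.35), given as log2 fold change ± SE, also fell. The remaining 3 places went to H2-Ea, which the annotation classes as a transcribed pseudogene, Btnl2 and H2-DMb2, which lie together on chromosome 17. Spon2 and Btnl2 passed in each of the 8 fits that left a library out. Ifi27l2a lost its call in 7 of them, and Ciita, Ighd, S100a8, Nckap5 and Mal in 6 each. Septin3, H2-Ea and H2-DMb2 lost theirs in 4 each and Nox4 in 3.

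Changed genes lay together in a stretch of chromosome 17 that holds the major histocompatibility complex. In the window from 34 to 37 Mb (GRCm38), 17 of 108 tested genes changed, 3 higher and 14 lower, where an even spread of the changed genes would give 2.88. H2-T23, a non-classical class I gene at 36029773 to 36032855, rose 4.55-fold, from 653 ± 78.2 to 2965 ± 271 normalized reads (n = 4 per group; adjusted p = 2.25e-06), and its neighbour H2-T22 rose too (log2 fold change 1.64 ± 0.11, adjusted p = 2.17e-05). H2-T10, at 36115876 to 36121465, fell from 1157 ± 84.6 to 475 ± 34.8 (adjusted p = 7.63e-05). Among class II genes, H2-Eb1, at 34305867 to 34316674, rose 5.76-fold (log2 fold change 2.53 ± 0.39, adjusted p = 0.00733) while H2-Aa (log2 fold change -1.60 ± 0.33, adjusted p = 0.0298), the annotated pseudogene H2-Ea (log2 fold change -2.08 ± 0.39, adjusted p = 0.0193) and H2-DMb2 (log2 fold change -1.88 ± 0.36, adjusted p = 0.0203) fell. Btnl2, a butyrophilin-like gene next to them at 34354822 to 34369495, was 4.18-fold lower (log2 fold change -2.06 ± 0.27, adjusted p = 0.00333). No set of 10000 shuffles of the changed genes over the tested genes gave as many in any 3-Mb window (permutation p = 0.0001, the smallest they can give; highest 13), and the next fullest window elsewhere, on chromosome 2, held 5. The shuffles treat genes as independent, so this p does not allow for neighbours that share reads or move together. It also measures no spread between animals. The window was chosen after the results were seen. Without its genes, and with p adjusted anew, 358 changed genes were counted. H2 genes resemble one another in sequence, so reads of one copy can be counted for another, and their single values are uncertain to that extent.

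**Figure D3:**
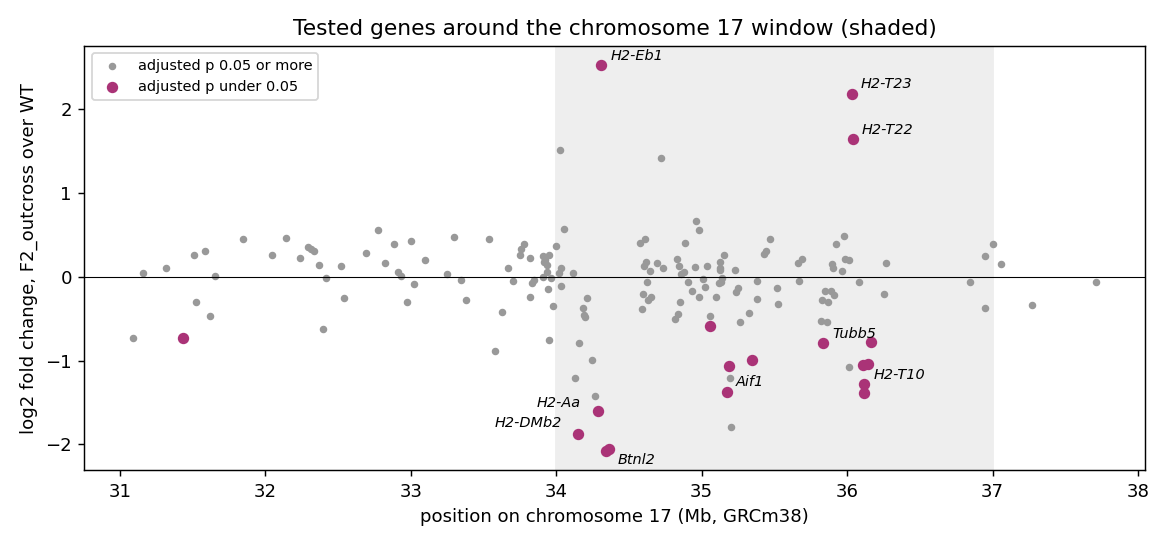
Log2 fold change, F2_outcross over WT, of tested genes by position on chromosome 17 (Mb, GRCm38), with the 3-Mb window shaded and genes past adjusted p 0.05 in colour. Within the window 3 changed genes lay above 0 and 14 below.

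Lists of amino acid and glucose genes passed camera with higher values in F2_outcross. Of the list for amino acid catabolism and the urea cycle, all 21 tested members had a positive fold change, and 4 of 21 tested members rose, 0 fell and 17 did not pass (9 higher and 0 lower adjusted over the list alone). The list rose as a set (median log2 fold change 0.30, camera adjusted p = 1.04e-08, adjusted p = 0.463 with an estimated correlation). Sds, which deaminates serine, rose from 6029.5 ± 322 to 10589 ± 825 normalized reads (adjusted p = 0.00255), Got1, the cytosolic aspartate aminotransferase, rose 1.82-fold (log2 fold change 0.87 ± 0.13, adjusted p = 0.00548), and Asl of the urea cycle 1.80-fold (log2 fold change 0.85 ± 0.17, adjusted p = 0.0241). Of the gluconeogenesis and fasting list, 3 of 13 tested members rose, 0 fell and 10 did not pass (4 higher and 0 lower adjusted over the list alone), and the set rose (median log2 fold change 0.38, camera adjusted p = 1.16e-05, adjusted p = 0.335 with an estimated correlation). Its changed members were Sds, Got1 and Gpt2, an alanine aminotransferase (log2 fold change 0.59 ± 0.13, adjusted p = 0.0342), and the first 2 of them also belong to the amino acid list. Of the glycolysis and glycogen list, 1 of 18 tested members rose, 0 fell and 17 did not pass (2 higher and 0 lower adjusted over the list alone), and the set rose (median log2 fold change 0.24, camera adjusted p = 0.00764, adjusted p = 0.526 with an estimated correlation). The call of this list was lost without F2_outcross replicate 2 (adjusted p = 0.117). Asl lost its call in 5 of the 8 fits that left a library out and Gpt2 in 6, and Sds and Got1 in none.

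Lists of fat synthesis and storage genes passed camera but neither an estimated correlation nor fry (fry adjusted p = 0.181 and 0.282). Of the fatty acid and triglyceride synthesis list, 2 of 21 tested members rose, 0 fell and 19 did not pass (6 higher and 0 lower adjusted over the list alone), and the set rose (median log2 fold change 0.34, camera adjusted p = 3.41e-05, adjusted p = 0.474 with an estimated correlation). Acacb, an acetyl-CoA carboxylase, rose 2.63-fold (log2 fold change 1.40 ± 0.18, adjusted p = 0.00285) and Thrsp, a regulator of lipogenesis, 2.29-fold (log2 fold change 1.19 ± 0.25, adjusted p = 0.0313). Elovl6 and Pnpla3 had log2 fold changes of 1.42 ± 0.37 and 1.26 ± 0.36 and did not pass (adjusted p = 0.0647 and adjusted p = 0.0820). Of the lipid droplet list, 1 of 14 tested members rose, 0 fell and 13 did not pass (6 higher and 2 lower adjusted over the list alone), and the set rose (median log2 fold change 0.32, camera adjusted p = 0.0322, adjusted p = 0.596 with an estimated correlation). Its changed member was Plin4. Cd36, a fatty acid transporter, had a log2 fold change of -0.59 ± 0.16 (adjusted p = 0.0676). The set's call was lost in 6 of 20 alternatives, with an adjusted p of 0.00462 to 0.163: a mean of at least 50, voom, and without WT replicate 3, WT replicate 4, F2_outcross replicate 2 or F2_outcross replicate 4. Thrsp lost its call in 4 of the 8 fits that left a library out, and Acacb and Plin4 in none. The list of fatty acid oxidation genes did not pass (adjusted p = 0.821). Its median (-0.05) and mean (-0.08) were negative while camera placed it upward, and 0 of its 28 tested members changed, over all genes or adjusted over the list alone.

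Some chaperone and clock genes changed. All 11 tested heat shock genes had a positive fold change, and 3 of 11 tested members rose, 0 fell and 8 did not pass (8 higher and 0 lower adjusted over the list alone). The set rose (median log2 fold change 0.44, camera adjusted p = 2.88e-07, adjusted p = 0.335 with an estimated correlation). Hsph1 rose 1.47-fold (adjusted p = 0.0180), Hspa8, the constitutive Hsc70 chaperone, 1.61-fold (adjusted p = 0.0447) and Chordc1, a co-chaperone, 1.36-fold (adjusted p = 0.0481). Of the clock genes that peak with Dbp and Per, 3 of 12 tested members rose, 1 fell and 8 did not pass (5 higher and 1 lower adjusted over the list alone), and the set rose (median log2 fold change 0.28, camera adjusted p = 0.0203, adjusted p = 0.474 with an estimated correlation). Usp2 rose from 694 ± 200.4 to 1789.7 ± 242 normalized reads (adjusted p = 0.00286), Ciart 2.30-fold (adjusted p = 0.0294) and Per2 2.26-fold (adjusted p = 0.0307), whereas Nr1d1, which encodes the repressor REV-ERB alpha, was 2.36-fold lower (log2 fold change -1.24 ± 0.24, adjusted p = 0.0209). The set's call was lost without WT replicate 1 (adjusted p = 0.0537) and with length and GC trends removed, and over the alternatives its adjusted p ran from 0.00543 to 0.0537. Of the 4 tested clock genes that peak with Bmal1, too few for a set test, 1 rose and 3 did not pass (1 higher and 1 lower adjusted over the list alone). Cry1, a repressor of the clock, rose from 275 ± 6.27 to 586 ± 81.3 (adjusted p = 0.000861), and Arntl, which encodes BMAL1, had a log2 fold change of -0.61 ± 0.20 (adjusted p = 0.108). Hsph1 lost its call in 4 of the 8 fits that left a library out, Hspa8 in 6, Chordc1 in 6, Ciart in 4, Per2 in 5 and Nr1d1 in 3, and Usp2 and Cry1 in none. Over all 20 alternatives Hspa8 lost its call in 9 and Chordc1 in 10.

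Genes that mark sex and zone of the liver moved in part. Of the female-biased genes, 3 of 17 tested members rose, 0 fell and 14 did not pass (8 higher and 0 lower adjusted over the list alone), and the set rose (median log2 fold change 0.34, camera adjusted p = 0.00178, adjusted p = 0.463 with an estimated correlation). Cyp2a4 rose 2.07-fold (log2 fold change 1.05 ± 0.19, adjusted p = 0.0187) and Cux2, a female-specific transcription factor, 2.00-fold (log2 fold change 1.00 ± 0.21, adjusted p = 0.0315). Cyp2a4 and the Cyp3a genes have close paralogs, so their counts are uncertain. The male-biased list did not pass (median 0.21, adjusted p = 0.171; 0 of 16 changed, over all genes or adjusted over the list alone). Of the periportal genes, 2 of 15 tested members rose, 0 fell and 13 did not pass (2 higher and 0 lower adjusted over the list alone), and the set rose (median log2 fold change 0.28, camera adjusted p = 0.000324, adjusted p = 0.463 with an estimated correlation). Its changed members were Sds and Gls2, the liver glutaminase (1.67-fold, adjusted p = 0.0274), which are also in the amino acid list. Of the pericentral genes, 2 of 12 tested members rose, 0 fell and 10 did not pass (4 higher and 2 lower adjusted over the list alone), and the set did not pass (median log2 fold change 0.14, camera adjusted p = 0.0873, adjusted p = 0.596 with an estimated correlation). Tbx3 rose 2.04-fold (adjusted p = 0.00940) and Slc1a2, a glutamate transporter, 1.75-fold (adjusted p = 0.0142). Cyp2a4 lost its call in 2 of the 8 fits that left a library out, Cux2 in 6 and Gls2 in 5, and Tbx3 and Slc1a2 in none.

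Lists of immune cell markers passed camera with lower values in F2_outcross. All 18 lymphocyte markers had a negative fold change, and 0 of 18 tested members rose, 4 fell and 14 did not pass (0 higher and 15 lower adjusted over the list alone). The set fell (median log2 fold change -1.11, camera adjusted p = 6.49e-10, adjusted p = 0.463 with an estimated correlation). Gzma, a granule protease of cytotoxic cells, fell from 74.5 ± 34.3 to 25.9 ± 6.08 normalized reads (adjusted p = 0.0304), Ighm, the heavy chain of immunoglobulin M, from 264 ± 81.6 to 123 ± 41.5 (adjusted p = 0.0333), and Igkc and Nkg7 fell as well (-0.99 ± 0.21 and -1.10 ± 0.26, log2 fold change ± SE). Immunoglobulin genes share sequence, so their single counts are uncertain. All 16 markers of Kupffer cells and macrophages had a negative fold change, and 0 of 16 tested members rose, 2 fell and 14 did not pass (0 higher and 15 lower adjusted over the list alone). The set fell (median log2 fold change -0.66, camera adjusted p = 1.06e-09, adjusted p = 0.463 with an estimated correlation), with Fcer1g 2.00-fold lower (adjusted p = 0.0181) and Tyrobp at -0.94 ± 0.22 (adjusted p = 0.0481). Of the neutrophil markers, 0 of 5 tested members rose, 1 fell and 4 did not pass (0 higher and 4 lower adjusted over the list alone), and the set fell (median log2 fold change -1.29, camera adjusted p = 0.00230, adjusted p = 0.474 with an estimated correlation). The member that fell was S100a8. The red blood cell markers also fell as a set (median log2 fold change -0.90, camera adjusted p = 0.00764, adjusted p = 0.526 with an estimated correlation), though 0 of 5 tested members rose, 0 fell and 5 did not pass (0 higher and 2 lower adjusted over the list alone). Gzma lost its call in 6 of the 8 fits that left a library out, Igkc in 6, Ighm in 6, Nkg7 in 6, Fcer1g in 3, Tyrobp in 7 and S100a8 in 6. The labels give the tissue as liver and the cell type as hepatocyte, and markers of sinusoidal endothelium (median 0.06, adjusted p = 0.396) and of stellate cells (median -0.02, mean 0.10, camera upward, adjusted p = 0.453) did not pass. None of these 17 and 16 genes changed over all genes tested, and 0 and 1 passed adjusted over the list alone.

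With lymphocyte markers at a median log2 fold change of -1.11, other lists passed camera with lower values in F2_outcross. Of the interferon response genes, 0 of 23 tested members rose, 1 fell and 22 did not pass (0 higher and 7 lower adjusted over the list alone), and the set fell (median log2 fold change -0.50, camera adjusted p = 7.87e-06, adjusted p = 0.526 with an estimated correlation). Ifi47, an interferon-induced GTPase, was 1.89-fold lower (log2 fold change -0.92 ± 0.21, adjusted p = 0.0380), and Irf7 had a log2 fold change of -0.72 ± 0.20 (adjusted p = 0.0717). Of the cytosolic ribosomal protein genes, 76 of 78 had a negative fold change and 0 of 78 tested members rose, 1 fell and 77 did not pass (1 higher and 48 lower adjusted over the list alone). The set fell (median log2 fold change -0.34, camera adjusted p = 3.88e-19, adjusted p = 0.463 with an estimated correlation). Rps12 was the member that fell, from 2073 ± 329 to 1399.7 ± 184 (adjusted p = 0.0397), and Rps24 had a log2 fold change of -0.53 ± 0.13 (adjusted p = 0.0547). The 2 members with a positive fold change, named after their values were seen, were Rps2 (1.39 ± 0.43, adjusted p = 0.0964) and Rps18 (0.26 ± 0.12, adjusted p = 0.237). Ifi47 lost its call in 6 of the 8 fits that left a library out and Rps12 in 6. Ribosomal protein genes have many near-identical pseudogenes that can take their reads. The proliferation list fell as a set (median log2 fold change -0.52, camera adjusted p = 0.0120, adjusted p = 0.676 with an estimated correlation), with 0 of 19 tested members changed (1 higher and 5 lower adjusted over the list alone), and lost its call without F2_outcross replicate 2 or F2_outcross replicate 4, its adjusted p running from 1.21e-05 to 0.128 over the alternatives. The nuclear oxidative phosphorylation genes fell as a set by a small amount (median log2 fold change -0.08, camera adjusted p = 0.0128, adjusted p = 0.769 with an estimated correlation), with 0 of 73 members past the threshold over all genes or adjusted over the list alone. With length and GC trends removed their median was 0.02 (adjusted p = 0.901). Over 20 alternatives the adjusted p ran from 2.04e-05 to 0.901, and the call was also lost with library weights and without WT replicate 2, F2_outcross replicate 1 or F2_outcross replicate 3.

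**Figure D4:**
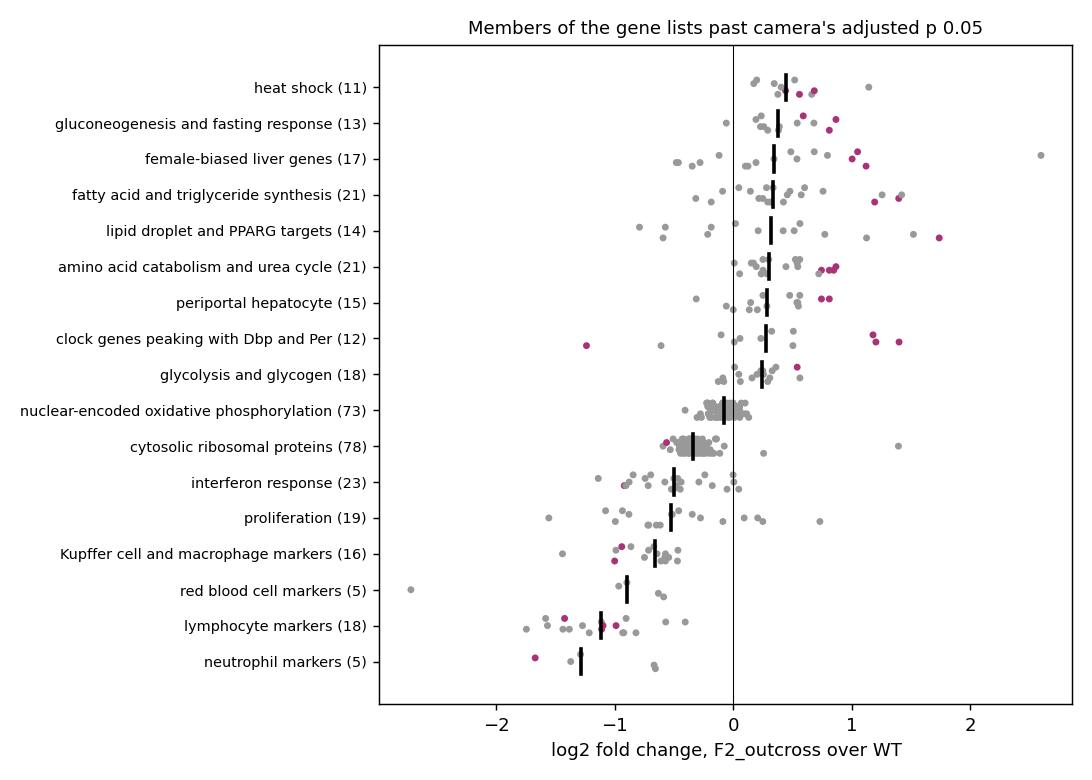
Log2 fold change, F2_outcross over WT, of each tested member (points, coloured where the adjusted p was under 0.05) of the 17 gene lists past camera's threshold, with the number of tested members in parentheses and the list median as a bar. Medians ran from -1.29 for neutrophil markers to 0.44 for heat shock genes.

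Of 36 lists tested, 17 passed camera with a preset correlation of 0.01, 9 higher and 8 lower. None of the 17 passed with the correlation estimated from these libraries, and 4 passed fry, which asks whether a list's genes move one way on balance: heat shock, gluconeogenesis, amino acid catabolism and periportal genes. In a check added after the results were seen, the mean of each list per library was compared over the 70 assignments of the libraries. The smallest exact p of 0.0286 was reached by 8 lists, 7 of them past camera, and Benjamini-Hochberg adjustment over the 36 lists gave 0.129 at best.

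Among lists that did not pass, single genes changed. In the xenobiotic list, 2 of 26 tested members rose, 0 fell and 24 did not pass (3 higher and 0 lower adjusted over the list alone). They were Nr1i2, which encodes the pregnane X receptor (log2 fold change 0.63 ± 0.11, adjusted p = 0.0121), and Por, the reductase that serves cytochromes P450 (log2 fold change 0.75 ± 0.16, adjusted p = 0.0313), and the set had an adjusted p of 0.0976. In the bile acid list, 1 of 22 tested members rose, 0 fell and 21 did not pass (1 higher and 0 lower adjusted over the list alone), the member being Cyp7a1 (set adjusted p = 0.0512). In the lipoprotein list, 0 of 22 tested members rose, 1 fell and 21 did not pass (1 higher and 1 lower adjusted over the list alone), the member being Sort1, a sorting receptor (log2 fold change -0.97 ± 0.13, adjusted p = 0.00392; set adjusted p = 0.388). In the unfolded protein and integrated stress list, 0 of 22 tested members rose, 1 fell and 21 did not pass (0 higher and 1 lower adjusted over the list alone), the member being Trib3, a pseudokinase induced by ATF4 (log2 fold change -1.26 ± 0.24, adjusted p = 0.0210; set adjusted p = 0.370). In the acute phase list, 1 of 25 tested members rose, 0 fell and 24 did not pass (1 higher and 0 lower adjusted over the list alone), the member being Orm3, whose counts are uncertain because of its near-identical copies (log2 fold change 0.71 ± 0.16, adjusted p = 0.0407; set adjusted p = 0.120). Among cholangiocyte markers, 1 of 6 tested members rose, 0 fell and 5 did not pass (1 higher and 0 lower adjusted over the list alone), the member being Spp1, osteopontin (log2 fold change 1.08 ± 0.21, adjusted p = 0.0247; set adjusted p = 0.191). In the growth hormone, IGF and insulin list, 1 of 14 tested members rose, 0 fell and 13 did not pass (2 higher and 3 lower adjusted over the list alone), the member being Bcl6. Cish, a feedback inhibitor induced by STAT5, had a log2 fold change of -2.10 ± 0.54 and did not pass (adjusted p = 0.0622; set adjusted p = 0.921). Por lost its call in 6 of the 8 fits that left a library out, Trib3 in 5, Orm3 in 6, Spp1 in 3 and Bcl6 in 5, and Nr1i2, Cyp7a1 and Sort1 in none.

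The remaining tested lists held no changed gene. Cholesterol synthesis genes had a median log2 fold change of -0.11 (adjusted p = 0.576; 0 passed adjusted over the list alone), mitochondrially encoded genes -0.10 (adjusted p = 0.287; 0 adjusted over the list alone), and immediate early genes -0.21 (adjusted p = 0.713; 0 adjusted over the list alone). Imprinted genes had a median of 0.01 (adjusted p = 0.453; 2 higher and 0 lower adjusted over the list alone). Genes of one-carbon metabolism and DNA methylation had a median of 0.13 but a mean of -0.11, with camera upward (adjusted p = 0.921; 2 higher and 2 lower adjusted over the list alone). Genes of small RNA processing had a median of -0.06 (adjusted p = 0.921; 2 higher and 2 lower adjusted over the list alone). All 11 exocrine pancreas markers had a negative fold change, with a median of -0.77, and the list did not pass (adjusted p = 0.127; 0 adjusted over the list alone).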

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

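The check for single libraries far from their group was planned, and the genes it covered were those the comparison had called. It was applied to 59 named genes past the threshold and 3 measures of the libraries, 124 groups of 4 in all, of which 9 stood out. Chance alone would single out about 1 in 20 groups, or 6.2 here. Reads on lines with no gene symbol made up 1.22% in WT replicate 2 and 0.614% to 0.674% in the other WT libraries. In normalized reads, Bcl6 was 174 in F2_outcross replicate 3 and 1511 to 1553 in the other 3 libraries of its group, Ciita was 138 in F2_outcross replicate 3 and 27.8 to 36.0 in the other 3 libraries of its group, and Spon2 was 15.6 in F2_outcross replicate 3 and 34.5 to 40.4 in the other 3 libraries of its group. Nrg4 was 1083 in F2_outcross replicate 2 and 751 to 774 in the other 3 libraries of its group, Cry1 was 708 in F2_outcross replicate 2 and 534 to 553 in the other 3 libraries of its group, and Rps12 was 1676 in F2_outcross replicate 2 and 1299.8 to 1314 in the other 3 libraries of its group. Rps12 was 2565 in WT replicate 1 and 1887 to 1939.9 in the other 3 libraries of its group, and Acacb was 1739 in WT replicate 2 and 1267 to 1301 in the other 3 libraries of its group. WT replicate 2 also lay nearest the other group on the first principal component.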

How the results depend on the processing

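The alternatives with log2 values as deposited, voom, length and GC trends and the chromosome 17 window were chosen after the data were seen, and the others were planned. No paired analysis was possible because the labels pair no animals across the groups, and the replicate numbers used here do not pair them either. Planned edgeR and DESeq2 tests were not run. The 383 changed genes numbered 302 to 525 under the other scalings, pseudocounts, filters, moderation, voom, trend removal and window removal. With library weights 1709 changed (genes higher in F2_outcross 809, genes lower in F2_outcross 900), and at an adjusted p under 0.10 1073 (543 higher, 530 lower). The cause of the first was not tested, and the second is a looser threshold. Voom on recovered reads called 349, 340 of them among the 383. Leaving out 1 library gave 108 to 1077 changed genes, 69 to 497 higher and 34 to 580 lower, with the lowest without F2_outcross replicate 2 or WT replicate 4, the highest without WT replicate 2, and the cause not tested. The fit without WT replicate 2 called 379 of the 383. The 17 lists past the threshold became 0 with an estimated correlation and 4 by fry, which take the correlation of list members from these libraries, and 13 to 20 without 1 library. The spread ratio turned positive without WT replicate 1 (0.02) and WT replicate 2 (0.41), from -0.20 without F2_outcross replicate 3 to the last of these, and it never passed the threshold; the cause was not tested. Of 59 named genes past the threshold, 19 passed in all 8 fits that left a library out. Over the 12 other alternatives named genes lost a call 33 times and gained one 48 times, and none that passed changed sign. Gene lists lost a call 5 times and gained one 10 times there. Values past the threshold in neither setting changed sign 3 times for genes and 25 times for lists. Khdc3, at 0 or 1 read, is limited by depth.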

Other observations

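The comparisons with other splits of the libraries were planned, and the tests on the chromosome 17 window, the pseudogenes, the H2-T sum, the length and GC trends, the cell-type markers, feeding and the hour were chosen after the results were seen. Of the 35 ways to split the 8 libraries into 4 and 4, only the real one, 1 of 35, gave as many as 383 changed genes, and the highest other split gave 2. The same held for the 230 higher and the 153 lower genes (1 of 35 each, highest other 2). A share of 1 in 35 is the smallest that these splits can give, so chance in forming the groups is not excluded. Every other split mixes the 2 groups, so low counts there would follow from any difference between them, whatever its source. The 17 gene lists did not stand apart, since 10 of the 35 splits gave as many and the highest other gave 22.

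Some pseudogenes of 2 ribosomal protein genes that lie beside the histocompatibility genes changed, in opposite directions. Rps18-ps1, on chromosome 4 at 71370738 to 71371196, went from 6.35 ± 3.32 to 68.2 ± 7.33 normalized reads (mean ± SD, n = 4 per group; log2 fold change 3.34 ± 0.33, limma adjusted p = 0.000609). Rps18-ps6, on chromosome 13 at 97760087 to 97760609, went from 3239 ± 386 to 1259 ± 126 (-1.36 ± 0.11, adjusted p = 0.000103), and Rps18-ps5 also fell (-0.68 ± 0.11, adjusted p = 0.00984). Rps18 itself, on chromosome 17 at 33951999 to 33956001, had a log2 fold change of 0.26 ± 0.12 (adjusted p = 0.237), and the sum of Rps18 and its named pseudogenes was lower by a log2 difference of -0.36 (two-sided exact permutation p = 0.0286). Gm10263, a copy of Rps28 on chromosome 13, fell as well (log2 fold change -1.51 ± 0.16, adjusted p = 0.000861). Other copies did not pass: Rps18-ps3 (0.11 ± 0.19, adjusted p = 0.794) and, for Rps28, Gm20568 (-0.26 ± 0.26, adjusted p = 0.606), Gm10443 (-0.01 ± 0.15, adjusted p = 0.976) and Gm13192 (0.02 ± 0.50, adjusted p = 0.987).

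Among the changed genes on chromosome 17, the 3 that rose (H2-T23, H2-T22 and H2-Eb1) had log2 fold changes of 1.64 or more. Each, less 2 SE, was 1.42 or more, where endothelial and stellate markers shifted by 0.09. These rises were larger than that shift. The genes were picked for being higher, so their lying above it is no test in itself. A lower share of immune cells would lower a gene or raise it by about that shift. The size of the rises argues against it for these 3 genes alone. For the 14 that fell (median -1.18) a lower share of immune cells cannot be told apart from other causes. They were picked for being lower, and immune markers fell too. A mere exchange of reads between H2-T copies would keep their sum, and the sum of 8 H2-T-like genes rose by 0.51 on the log2 scale (exact permutation p = 0.0286). These 8 were chosen after the results were seen, so this p adds no weight. Reads exchanged with genes outside the 8, or left uncounted, could also change the sum and were not tested. A difference in DNA sequence between the groups in this region stays open: of pseudogenes elsewhere that were matched to a parent gene in the window or within 1 Mb of it, 2 of 9 were called (Rps18-ps1 and Gm10263) against 12 of 891 others (Fisher's exact p = 0.00761), but the margin was set after these were seen, and Rps18-ps5 and Rps18-ps6, also called, were not in the matching, so this carries no weight. With parents inside the window alone 0 of 2 were called, too few to decide, and the ancestry that defines the groups stays open and untested.

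For the lower ribosomal and immune lists, trends with gene length and GC content may add to the ribosomal change. The median of the ribosomal protein genes was -0.34 before and -0.26 after these trends were removed (camera with the preset correlation, adjusted p = 4.23e-16 after removal). An estimated correlation was not used after removal, so whether the trends are the whole of the change cannot be told. The list before removal had an adjusted p = 0.463 with an estimated correlation and 0.105 by fry, so its fall itself is uncertain. A higher share of hepatocytes would lower the markers of every other cell type alike. Lymphocyte and macrophage markers fell relative to endothelial and stellate markers by a log2 difference of -1.04 (two-sided exact permutation p = 0.0286, the smallest possible). The immune lists were picked after they were seen to fall, so this p adds no weight. Endothelial and stellate markers themselves shifted by 0.09 (exact permutation p = 0.2) and were not lower. This argues only against a higher share of hepatocytes that lowers all other cell types alike. Unequal shifts of the other cell types are not excluded. A change in the immune cells themselves, and ancestry, stay open and untested.

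For the fuel and clock genes, a longer fast would lower the fatty acid and triglyceride synthesis genes, but their mean per library was higher in F2_outcross by 0.47 (log2, two-sided exact permutation p = 0.0571). A shorter fast would lower the gluconeogenesis and fasting genes, but their mean was also higher, by 0.42 (exact permutation p = 0.0571). Both lists were compared in this way after they were seen to rise, so these p-values add no weight. Neither value passed the threshold, and neither fast is ruled out. A different hour of collection would move clock genes both ways, as Nr1d1 (-1.24) and the 4 changed clock genes that rose did. Of the clock genes that did not pass, some lay near 0: Dbp (-0.10 ± 0.15), Nr1d2 (0.01 ± 0.12), Per1 (0.06 ± 0.27), Clock (0.09 ± 0.11) and Nfil3 (0.14 ± 0.19, log2 fold change ± SE). Others lay further away: Tef (0.50 ± 0.15), Per3 (0.51 ± 0.22), Hlf (0.32 ± 0.12), Cry2 (0.23 ± 0.15), Bhlhe41 (-0.61 ± 0.28) and Arntl (-0.61 ± 0.20). All of these but Clock, Nfil3 and Arntl were named after their values were seen. Because no hour or feeding state is given in the sources used here, these cannot be told apart from ancestry.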
